A study of Mus musculus with 12 samples.

How the data were processed

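The series holds RNA sequencing of mouse LSK cells, the Lin-negative, cKit-positive, Sca1-positive fraction of bone marrow that contains the blood stem and progenitor cells. Cells of wild type (WT) mice and of conditional Mettl3 knockout (cKO) mice were infected with a lentivirus carrying SON and GFP or with the empty GFP vector. GFP-positive cells were sorted 48 h after infection. Per the labels, RNA was extracted with TRIzol and phenol-chloroform and libraries were made with SMART-Seq v4, a full-length cDNA kit whose reads carry no strand. There were 4 groups of 3 libraries each: WT vector, WT SON, cKO vector and cKO SON. The labels do not say that replicates came from separate animals, so every p-value measures only the spread between these samples.

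Per the labels and the values themselves, the deposited gene table holds raw read counts per Ensembl gene, with 2 further entries for the lentiviral SON construct. The deposited table of transposable elements (TE) likewise holds raw read counts per subfamily, without positions. The deposited splicing table holds percentages from 0 to 100 per event and library (percent inclusion of an exon, percent retention of an intron, or percent use of a splice site), although its column names end in counts. The table holds no read numbers, so the depth behind each percentage is unknown and no interval could be given. The submitters' processing notes name TopHat, cutadapt 4.1, STAR 2.7.10b and HTSeq 2.0.2 and the mm10 assembly without saying which step used which tool. How reads were divided among TE subfamilies, which program called the splicing events and which strand setting was used are not stated.

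The gene table had 43434 entries, of which 42462 had an identifier in the GENCODE M21 annotation of GRCm38 (mm10). Of 4134 missing symbols, 3164 were filled from that annotation. Gene positions in the text come from it, because the positions in the deposited gene table were not those of GRCm38: 1310 of 39298 gene starts matched. Positions of the splicing events did match GRCm38. Counts of genes that overlap on opposite strands, and of pseudogenes and close paralogs, are uncertain with unstranded reads.

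Total gene counts ranged from 29024140 to 43601769 per library. A gene with 0 counts in a group is given as a bound against a floor of 3 counts over that group. Intervals and floors cover counting error only, since reads from amplified cDNA without molecular identifiers are not independent molecules. Levels are given as CPM, the count of a gene scaled to a fixed total over the tested genes after correction by the trimmed mean of M values (TMM), as mean ± SD with n = 3 libraries per group.

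Genes were tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) on all 12 libraries with 1 coefficient per group, TMM scaling and the filterByExpr filter (minimum count 10, minimum total 15). This left 17259 genes, without the construct. The comparisons were SON against vector in WT and in cKO, cKO against WT with vector and with SON, and the genotype by SON interaction. All tests were two-sided with Benjamini-Hochberg adjustment over the tested genes, and a gene was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors from the edgeR fit. TEs were tested in the same way with the library sizes and TMM factors of the gene table, 774 subfamilies in all. Splicing percentages were tested with limma 3.58.1 for the 252302 of 661162 events with a value in all 12 libraries and some variation, and called at an adjusted p under 0.05 with a difference of at least 10 percentage points.

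Gene lists fixed beforehand were tested with camera from limma at its preset correlation of 0.01, with adjustment over the 19 lists. They covered interferon response, nucleic acid sensing, NF-kappaB inflammatory genes, Myc targets of ribosome biogenesis, ribosomal proteins, the cell cycle, p53 targets, Atf4 stress targets, immediate early and handling genes, the m6A machinery, splicing factors and speckle proteins, transcripts with SON-sensitive splicing, stem cell genes, and markers of neutrophils and monocytes, megakaryocytes and erythroid cells, mast cells and basophils, lymphoid cells, macrophages and dendritic cells, and stroma and endothelium. Each test was repeated with an estimated correlation and with fry. All 482 list entries matched a gene in the table. In addition, chosen after the data were seen, a score per library (the mean log2 CPM of a list, each member centred on its mean) was compared by exact permutation tests.

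The comparisons, tests, filters, lists, other settings to be tried and the rule for naming genes were fixed before the data were examined. The rule named Son, Mettl3 and Myc always. It also named, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean CPM of at least 5, no overlap between the groups and a symbol that is not a predicted, clone or pseudogene name, and up to 4 members of each list with the smallest p. For TEs it named the 5 largest rises and falls with a mean count of at least 20, and for splicing the 5 largest differences each way in events with a gene symbol. Where none passed, the 5 with the smallest p are given as values that did not pass.

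The other settings fixed in this way were DESeq2 1.42.0, RLE size factors, no count filter, a stricter filter, only the groups compared, the replicate number as a block, leaving out each library in turn, TMM on the TE table, a logit scale (shift 0.01), minimum differences of 5 and 20 points, an SD filter of 2 points and events with values in at least 2 libraries per group. Settings chosen after seeing the data were the SON effect averaged over both genotypes, a correction for GC content, genes without a GC-rich stretch (the richest 200-base window of the transcript under 65% GC), and fits without 2 or 3 libraries that stood apart. Where an arm had fewer libraries, the spread was pooled over the groups. The replicate numbers gave no consistent pairing: 6 of 12 libraries correlated best with a library of their own number, and the 18 same-number pairs had a median r of 0.009. Same-number pairs of vector and SON libraries had r of -0.568, -0.604 and 0.159 in WT and 0.198, 0.092 and 0.145 in cKO. In WT the highest values joined libraries of different number: WT vector 2 with WT SON 1 (r = 0.661) and WT vector 1 with WT SON 2 (r = 0.558). Pairing by number within cKO and pairing across numbers within WT are therefore not excluded. The latter was not modelled, and it cannot be told apart from a shared level of GC-rich transcripts.

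The methods were tested on simulated data made from these libraries. edgeR recovered 8% of genes changed by 1 log2 unit and 50% of those changed by 2, with 4 unchanged genes called. For TEs the shares were 88% and 100%, with 6 unchanged TEs called. For splicing, 0% of shifts of 10 points and 3% of shifts of 20 points were recovered, with 1 unchanged event called. A list shifted by 0.5 was called by camera with an adjusted p of 5.29e-14 and 0 other lists were called. The simulated genes varied independently, so this says nothing about false calls for lists whose members vary together. In the data, interferon-response genes without a GC-rich stretch had an estimated correlation of 0.646 for SON in WT. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The construct entries and events without a value in some library were left out of the main tests.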

Results

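RNA from LSK cells, the mouse bone marrow fraction that holds blood stem and progenitor cells, was sequenced 48 h after lentiviral infection. The cells were WT or carried a conditional knockout (cKO) of Mettl3, the catalytic subunit of the complex that writes m6A into mRNA, and received either SON, a large nuclear speckle protein that promotes splicing, or an empty GFP vector. There were 3 libraries each of WT vector, WT SON, cKO vector and cKO SON. Libraries are named by group and replicate number. Total gene counts were 43601769, 31210796 and 38892622 in WT vector 1, 2 and 3, 41684225, 38743976 and 35478019 in WT SON, 33245320, 32118889 and 39425613 in cKO vector, and 29024140, 35209375 and 33816294 in cKO SON. Read counts per gene, read counts per TE subfamily and splicing percentages per event were available for all 12 libraries.

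Mettl3 transcripts fell in cKO cells with both viruses. The gene lies on chromosome 14, 52294841 to 52305128, minus strand, and had 70.9 ± 11.9 CPM in WT vector, 70.3 ± 9.95 in WT SON, 30.8 ± 4.17 in cKO vector and 25.6 ± 2.11 in cKO SON (mean ± SD, n = 3). The log2 fold change between genotypes was -1.20 ± 0.18 (SE) with vector (adjusted p = 0.00818) and -1.46 ± 0.18 with SON (adjusted p = 0.00215), and both calls held in all 12 fits that leave out 1 library. Inclusion of Mettl3 exon 4, read from an event on 52298640 to 52298736 inside that exon, averaged 92.1% ± 2.73 in WT vector, 92.6% ± 1.80 in WT SON, 71.2% ± 4.37 in cKO vector and 59.3% ± 8.27 in cKO SON. This event passed with SON (difference -33.24 points ± 3.89, adjusted p = 0.0374) and did not with vector (difference -20.90 points, adjusted p = 0.303), and the difference between these was not called (interaction -12.34 points ± 5.50, adjusted p = 0.834). With SON it passed in 4 of the 12 fits that leave out 1 library. Retention of the Mettl3 intron between exons 8 and 9, on 52296582 to 52296663, rose by 10.54 points ± 0.58 with vector, from 7.69% to 18.2% (adjusted p = 0.00113). With SON it was 7.82% in WT and 16.7% in cKO, a difference under the minimum of 10 points.

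The viral SON transcript, read from 1 of the 2 construct entries, made up 1.29% ± 0.377 of all counts in WT SON and 2.59% ± 0.322 in cKO SON (mean ± SD, n = 3). Every cKO SON library was above every WT SON library, and the exact permutation p, two-sided, was 0.1, the smallest that 3 against 3 libraries can give. Vector libraries held 3 to 20 reads of that entry. The other entry had nearly equal counts, such as 412222 beside 415074 in WT SON 1, and was left out of the total. The labels do not say what the 2 entries stand for, and the share would be larger if both hold construct reads. Endogenous Son, on chromosome 16 from 91647506 to 91679221, was not called in any comparison of all libraries: its log2 fold change was 0.09 ± 0.27 for SON in WT (adjusted p = 1), -0.28 ± 0.27 for SON in cKO (0.981), -0.09 ± 0.27 for cKO with vector (0.853) and -0.47 ± 0.27 for cKO with SON (0.212). Without WT vector 2, WT SON 1 and cKO vector 1 it passed between genotypes (adjusted p = 0.0113 with vector and 0.0087 with SON). Reads of coding sequence shared with the construct leave the endogenous value uncertain in SON libraries. Myc, a growth regulator whose mRNA carries m6A, was likewise not called, with -0.15 ± 0.47 for SON in WT, -0.32 ± 0.47 for SON in cKO, 0.22 ± 0.47 for cKO with vector and 0.05 ± 0.47 for cKO with SON.

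**Figure D1:**
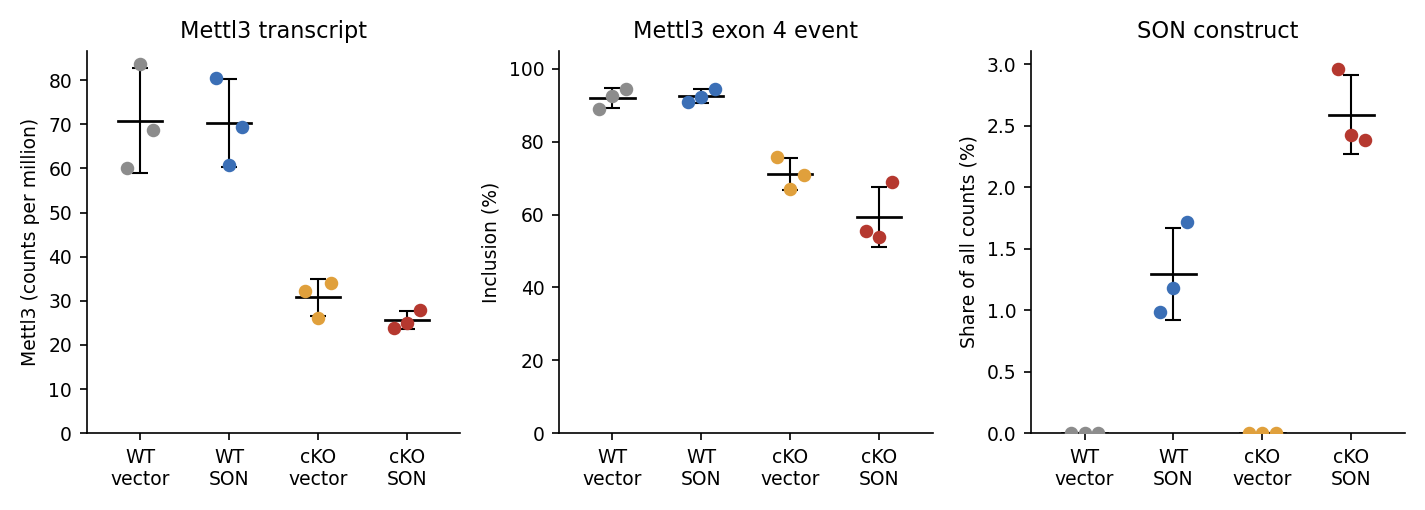
Mettl3 level in CPM, Mettl3 exon 4 inclusion in percent and the viral SON transcript as a percent of all counts in the 4 groups, with 1 point per library, the mean as a line and bars of 1 SD. Mettl3 was 70.9 and 70.3 CPM in the WT groups and 30.8 and 25.6 CPM in the cKO groups.

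The libraries also differed in transcripts with a GC-rich stretch, and this moved with genotype. Genes were grouped by the richest 200-base window of their transcript, 75% GC or more against under 65%, a grouping chosen after the data were seen. The median log2 deviation of GC-rich genes minus that of GC-poor genes was -0.12, -1.14 and -0.43 in WT vector 1, 2 and 3, and -1.35, 0.01 and -0.81 in WT SON. It was -0.26, 0.87 and 0.79 in cKO vector, and 0.70, 0.86 and 0.81 in cKO SON. The genotype means were -0.64 and 0.63, a difference of 1.27 (two-sided exact permutation p = 0.01 within virus, smallest possible 0.005), and the 6 WT libraries alone spanned 1.36.

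**Figure D2:**
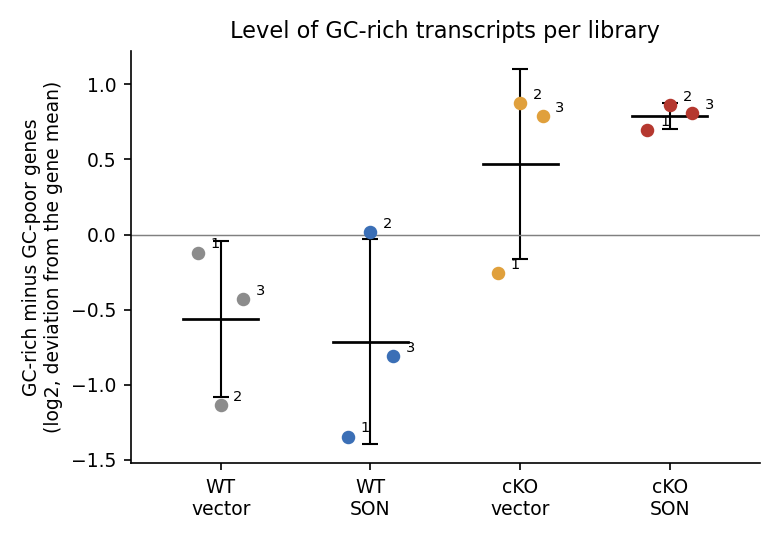
Median log2 deviation of genes with a GC-rich stretch minus that of genes without, for each library, numbered by replicate, with group mean and bars of 1 SD. WT libraries ranged from -1.35 to 0.01 and cKO libraries from -0.26 to 0.87.

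The comparison of cKO vector with WT vector asked what the Mettl3 knockout changed in cells that received the empty virus. Ubd, a ubiquitin-like protein induced by interferon and TNF, had no read in any WT vector library and was at least 1227-fold higher in cKO vector (floor of 3 counts over the group, mean 32.1 CPM). Foxs1, a forkhead transcription factor (chromosome 2, 152931898 to 152933208), rose by 6.20 ± 0.58 on the log2 scale (adjusted p = 6.63e-04). The metalloprotease gene Adamts1 rose by 5.62 ± 0.58 (adjusted p = 0.00113) and P3h4, a collagen-modifying factor, by 6.83 ± 1.13 (adjusted p = 0.0123). Mmrn1, encoding multimerin of megakaryocytes and stem cells (chromosome 6, 60924976 to 60989378), fell by 2.50 ± 0.22, from 45.4 to 8.01 CPM (adjusted p = 5.06e-04). Ighm, the immunoglobulin mu constant region, fell by 3.21 ± 0.50, from 2841 ± 1617 to 307 ± 170 CPM, and Ighv9-3, an immunoglobulin variable segment, had no read in cKO vector and was at least 574-fold lower.

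In all, 978 genes rose and 254 fell of 17259 tested, and 4765 of the tested genes, called or not, had no overlap between the groups, where chance gives 10%. That 10% is a weak reference, since genes can move together. SON against vector, with 0 genes called in either genotype, left 3889 genes without overlap in cKO and 1364 in WT. Further named rises were Cebpd, Cebpb, Jund, Tamalin, Timp2 and BC023105, with log2 fold changes of 5.39 to 6.33. Further named falls were Igkc at -2.95 ± 0.53, Jchain at -2.90 ± 0.58, the B cell coactivator Pou2af1 at -2.77 ± 0.64, Ly6d at -2.45 ± 0.56, and the neuropeptide genes Penk and Npy at -1.98 ± 0.45 and -1.89 ± 0.41. Igkv17-121 also fell, on reads of few libraries, and is given no fold here. Of the 10 named rises, P3h4, Cebpd, Cebpb, Jund, Tamalin and Timp2 carry a window of 75% GC or more. Ubd, Foxs1, BC023105 and the 10 named falls have a richest window under 65% GC. A separate fit of the 8249 genes of that kind called 754, of which 423 are among the 1232. Calls of Ubd, Foxs1, P3h4, Adamts1, Mmrn1 and Ighv9-3 held in all 12 fits that leave out 1 library. Ighm and Igkc lost theirs without cKO vector 2, with the count of called genes then at 131, and the other named genes passed in 1 to 9 of the 12 fits.

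Interferon-response genes were higher as a group in cKO vector. Of 52 tested members 16 rose and 1 fell (31 and 1 adjusted over the list alone), camera gave an adjusted p of 2.76e-10, and the adjusted p = 0.583 with an estimated correlation. Among them Bst2, which tethers virions, rose by 1.15 ± 0.15, Gbp2 by 1.73 ± 0.30, Rtp4 by 1.18 ± 0.23 and the ubiquitin-like modifier Isg15 by 1.54 ± 0.31. Of its 42 members without a GC-rich stretch, adjusted over such genes, 30 rose and 1 fell. Nucleic acid sensors had 4 of 20 members up and 0 down (5 and 0 adjusted over the list alone), including the RNA sensor Tlr3 at 1.60 and the adaptor Sting1 at 0.65 (camera adjusted p = 0.0402). NF-kappaB inflammatory genes had 6 of 22 up and 1 down (10 and 1 adjusted over the list alone), with the chemokines Cxcl2 at 1.65 and Ccl9 at 1.24 (camera adjusted p = 6.18e-04). Both lists had an adjusted p = 0.583 with an estimated correlation.

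Stem cell genes were also higher with vector: 8 of 28 rose and 0 fell (11 and 1 adjusted over the list alone), including the stem cell receptor Robo4 at 2.18 ± 0.31, Fgd5 at 2.93 ± 0.46, Hoxb5 at 2.55 and Ly6a, which encodes Sca1, at 1.08 (camera adjusted p = 0.00524). Of the 11 members without a GC-rich stretch 5 rose and 0 fell. Immediate early and handling genes had 3 of 15 up and 1 down (8 and 2 adjusted over the list alone), with Jund, Hspa1a at 3.31 and Dusp1 at 3.34 up and the mRNA-decay factor Zfp36 at -0.83 (camera adjusted p = 0.0493), and 1 tested member lacks a GC-rich stretch. Cell cycle genes were lower, with 2 of 31 down and 1 up (3 and 1 adjusted over the list alone): the proliferation marker Mki67 at -0.88 and the helicase subunit Mcm5 at -0.47 fell and the cyclin Ccne1 rose by 2.77 (camera adjusted p = 6.18e-04). Myc targets of ribosome biogenesis had 2 of 30 down and 1 up, both adjusted over all genes and adjusted over the list alone (Pes1 -0.55, Nop58 -0.48, Odc1 3.15, camera adjusted p = 0.038). These 4 lists each had an adjusted p = 0.583 with an estimated correlation. Ribosomal protein genes were lower as a group (camera adjusted p = 0.00372, adjusted p = 0.734 with an estimated correlation) although 0 of 60 were called by edgeR, adjusted over all genes or adjusted over the list alone, and the list did not pass among genes without a GC-rich stretch (camera adjusted p = 0.362).

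The other 11 lists did not pass with vector. Camera adjusted p was 0.963 for p53 targets (0 up and 1 down of 20, Ccng1 -0.53), for the m6A machinery (1 and 1 of 20, with the demethylase Alkbh5 at 2.52 beside Mettl3), for neutrophil and monocyte markers (0 and 1 of 23, Itgam -0.65) and for megakaryocyte and erythroid genes (3 and 2 of 21, the GATA cofactor Zfpm1 3.19, the transferrin receptor Tfrc -0.77). It was 0.486 for Atf4 targets (0 and 1 of 21), where the cystine transporter Slc7a11 fell by 1.19 ± 0.18. Splicing and speckle genes had 0.171 (2 and 0 of 35, Srsf9 3.55, Srsf2 2.76), SON-sensitive transcripts 0.409 (0 and 0 of 9), mast cell genes 0.0845 (0 and 0 of 13, Cpa3 -1.50 not called), lymphoid genes 0.254 (0 and 1 of 16, Ighm), macrophage and dendritic genes 0.291 (1 and 2 of 14, Vcam1 1.57, Itgax -1.69, Marco -1.21) and stroma 0.793 (1 and 2 of 10, Dcn 3.45, Lum -1.82, Col1a2 -1.74). For 6 of these lists (p53, Atf4, m6A, splicing, neutrophil and stroma) the median, mean and test differed in sign.

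The genes were tested with edgeR. DESeq2 called 2158 up and 1206 down, and the fit of only these 6 libraries 60. Leaving out 1 library changed the count of 1232 to 217, 507 and 188 without WT vector 1, 2 and 3, to 456 without WT SON 3, to 3104, 131 and 263 without cKO vector 1, 2 and 3, and to 412, 359 and 390 without cKO SON 1, 2 and 3. The 8 lists called became 5 without WT vector 3 and 4 without cKO vector 1.

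The comparison of cKO SON with WT SON asked the same of cells that received SON. P3h4 rose by 9.43 ± 1.29 on the log2 scale (adjusted p = 0.00335), Foxs1 by 6.54 ± 0.59 (adjusted p = 5.10e-04), Ubd by 6.24 ± 1.01 (adjusted p = 0.00794) and Fkbp10, a collagen chaperone next to P3h4 on chromosome 11 (100415697 to 100424824), by 5.42 ± 0.34 (adjusted p = 1.07e-04). Ighv9-3 fell by 7.93 ± 1.08, the light chain segment Iglv1 by 5.31 ± 1.04 and Ighm by 2.47 ± 0.48. Trgc1, a T cell receptor gamma constant region, fell by 2.71 ± 0.38 (adjusted p = 0.00351) and the cation channel gene Trpm2 by 2.48 ± 0.34 (adjusted p = 0.00339). Mmrn1 again fell, by 2.21, and the cystine transporter Slc7a11 fell by 1.87 ± 0.18 (adjusted p = 7.18e-04).

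With SON 2310 genes rose and 1895 fell, and 8642 of the 17259 tested genes, called or not, had no overlap between the groups (chance 10%, again a weak reference). Other named rises were Cebpd, Timp2, Nr2f6, Bloc1s4, Mapk11 and Zfp771 at 5.18 to 6.82. Other named falls were Ly6d at -2.56 ± 0.56, the deadenylase scaffold Cnot1 at -2.31 ± 0.49, Pou2af1 at -2.30 ± 0.63, the nuclear pore gene Nup188 at -2.29 ± 0.46 and Was at -2.23 ± 0.51. P3h4, Cebpd, Timp2, Nr2f6, Bloc1s4 and Zfp771 carry a window of 75% GC or more. The separate fit of genes without a GC-rich stretch called 1889, of which 1347 are among the 4205. Calls of P3h4, Foxs1, Ubd, Timp2, Fkbp10, Mapk11, Ighv9-3, Iglv1, Trgc1, Trpm2, Ighm, Cnot1 and Nup188 held in all 12 fits that leave out 1 library. Of the rest, Cebpd lost its call without WT SON 3, and Nr2f6, Bloc1s4 and Zfp771 without WT SON 1, WT SON 3 or cKO SON 2, while Ly6d and Pou2af1 passed in 9 and Was in 8 of the 12 fits.

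Stem cell genes were higher in cKO SON too: 13 of 28 rose and 0 fell (16 and 0 adjusted over the list alone), with Robo4 at 2.02, Fgd5 at 2.96, the endothelial and stem cell adhesion gene Esam at 2.01 and Slamf1, which encodes CD150, at 1.41 (camera adjusted p = 1.30e-04, adjusted p = 0.383 with an estimated correlation). Of the 11 members without a GC-rich stretch 8 rose and 0 fell. Cell cycle genes were lower, 16 of 31 down and 2 up (20 and 2 adjusted over the list alone), including Mcm5 at -0.86, the checkpoint kinase Bub1b at -0.92 and the topoisomerase Top2a at -0.98 (camera adjusted p = 1.56e-05, adjusted p = 0.383 with an estimated correlation), and 12 of the 16 members without a GC-rich stretch fell and 0 rose. Ribosomal protein genes had 20 of 60 down and 0 up (44 and 0 adjusted over the list alone), such as Rpl7a at -0.69 and Rpl4 at -0.57 (camera adjusted p = 5.46e-08, adjusted p = 0.507 with an estimated correlation). Myc targets of ribosome biogenesis had 13 of 30 down and 2 up (15 and 2 adjusted over the list alone), with Pes1 at -0.86, Ldha at -0.52 and Cdk4 at -0.47 (camera adjusted p = 0.00189, adjusted p = 0.440 with an estimated correlation).

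Camera called neutrophil and monocyte, mast cell and basophil, and lymphoid genes lower in cKO with SON. Neutrophil and monocyte genes had 4 of 23 down and 1 up (the same counts adjusted over the list alone), with the integrin Itgam at -1.14 and Ms4a3 at -0.88, while lysozyme Lyz2 was at 0.84 (camera adjusted p = 0.0371). Mast cell and basophil genes had 2 of 13 down and 1 up (3 and 1 adjusted over the list alone), with carboxypeptidase Cpa3 and the Fc receptor chain Ms4a2 each at -1.64 and granzyme Gzmb at 1.38 (camera adjusted p = 0.0387). Both had an adjusted p = 0.440 with an estimated correlation. Lymphoid genes had 2 of 16 down and 0 up, Ighm and Cd79b at -0.69 (the same counts adjusted over the list alone, camera adjusted p = 0.0387, adjusted p = 0.383 with an estimated correlation).

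The other 12 lists did not pass with SON. Interferon-response genes had 6 of 52 up and 3 down (camera adjusted p = 0.385), with Rtp4 at 1.10, Bst2 at 0.64 and the mono-ADP-ribosyltransferase Parp14 at -1.38. Among its 42 members without a GC-rich stretch, adjusted over such genes, 21 rose and 2 fell, and the list passed there at the preset correlation (camera adjusted p = 8.07e-06) but not with an estimated correlation (adjusted p = 0.508). The change in this list between vector and SON was tested as the interaction (camera adjusted p = 7.81e-15, adjusted p = 0.266 or more with an estimated correlation). The remaining values were 0.545 for nucleic acid sensors (2 up and 3 down of 20, Tlr3 1.63), 0.985 for NF-kappaB genes (3 and 4 of 22, Ccl9 1.40, Tnf -0.69), 0.823 for p53 targets (3 and 2 of 20, Pmaip1 -0.76), 0.0725 for Atf4 targets (2 and 7 of 21, Slc7a11, and Phgdh of serine synthesis at -0.79) and 0.426 for immediate early genes (5 and 3 of 15, Jund 5.17, Fos -1.11, Nr4a1 -1.59). They were 0.844 for the m6A machinery (4 and 4 of 20, with the demethylases Alkbh5 at 2.49 and Fto at -1.24), 0.340 for splicing and speckle genes (5 and 11 of 35, Tra2a -1.22), 0.162 for SON-sensitive transcripts (0 and 3 of 9, Fancg -0.78), 0.742 for megakaryocyte and erythroid genes (5 and 4 of 21, Nfe2 1.44, Tfrc -1.33), 0.0555 for macrophage and dendritic genes (0 and 4 of 14, Marco -1.39) and 0.737 for stroma (1 and 2 of 10). For p53, splicing, megakaryocyte and stroma genes the median, mean and test differed in sign.

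The edgeR count of 4205 fell to 1128 and 1206 without WT SON 1 and 3, and to 1506, 1260 and 1770 without cKO SON 1, 2 and 3. The 7 lists called became 4 without WT SON 3 and 4 without cKO vector 1. Per-library list scores, compared between genotypes by exact permutation within virus (two-sided, adjusted over the 19 lists, smallest unadjusted p 0.005), were higher in cKO for stem cell genes by 0.96, interferon-response genes by 0.56, NF-kappaB genes by 0.60 and immediate early genes by 1.51 (adjusted exact p = 0.0238 each). They were higher for p53 targets by 0.53 and megakaryocyte and erythroid genes by 0.24 (0.0317 each), higher for the m6A machinery by 0.46 and lower for mast cell genes at -0.85 (0.0475 each). Restricted to members without a GC-rich stretch, the difference was 0.64 for stem cell genes (unadjusted exact p = 0.01), 0.56 for interferon genes (0.005) and 0.32 for NF-kappaB genes (0.255), while the sign turned for p53 targets (-0.10), megakaryocyte and erythroid genes (-0.22) and the m6A machinery (-0.24). Immediate early genes had 1 tested member of that kind, too few for such a score, so their difference cannot be told apart from the GC gradient.

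**Figure D3:**
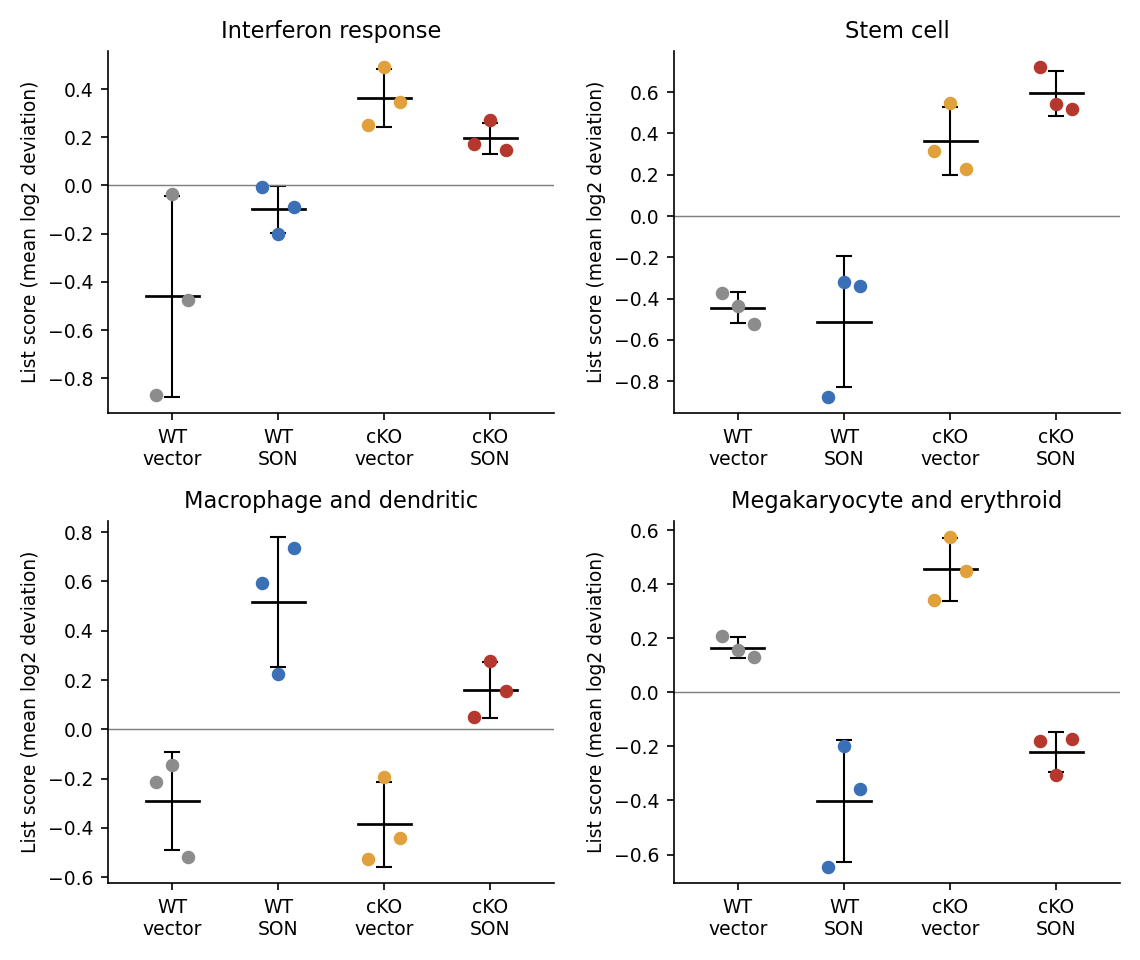
Mean log2 score of the interferon response, stem cell, macrophage and dendritic, and megakaryocyte and erythroid lists in each library, with group mean and bars of 1 SD. Stem cell scores were higher in cKO by 0.96, and with SON macrophage scores were higher by 0.68 and megakaryocyte and erythroid scores lower, at -0.62.

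The genotype effect with vector was then set against that with SON, to see whether added SON changed it. Of the 978 rises with vector 879 also rose with SON, where 2310 rose (130.9 by independence), and 202 of the 254 falls also fell, where 1895 fell (27.9 by independence), while 1 gene went opposite ways. Across the 17259 genes the log2 fold changes had a Pearson r of 0.815, a Spearman rho of 0.816 and a slope of 0.925, where simulated noise gave 0.005. Genes are not independent replicates, and this is 1 of 4 such relations computed. Both contrasts run along the GC gradient, and among genes without a GC-rich stretch r was 0.686.

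**Figure D4:**
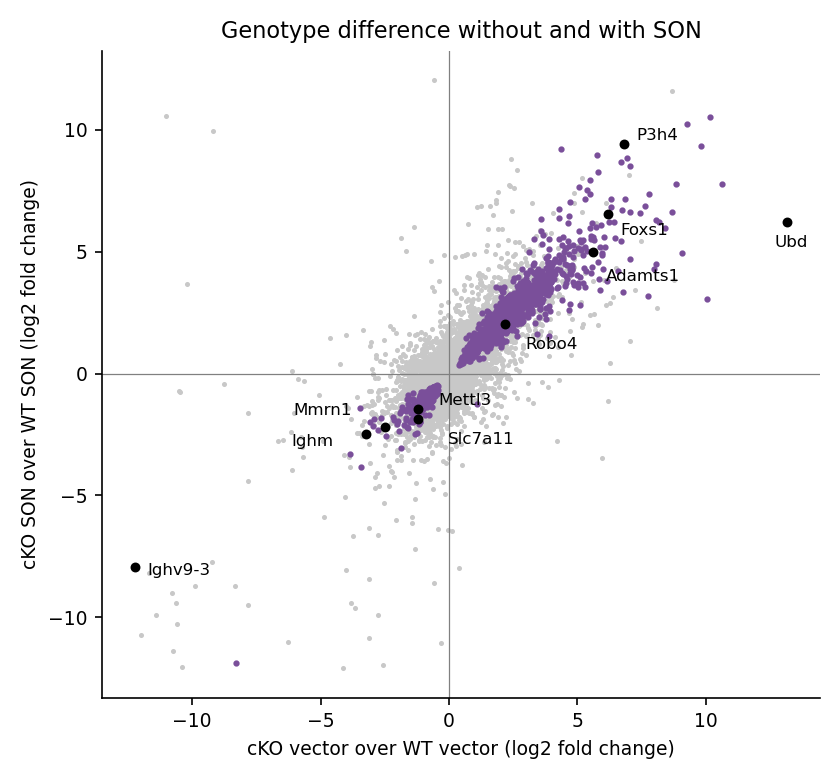
Log2 fold change of cKO against WT for each tested gene, with vector on the horizontal and with SON on the vertical axis, genes called in both in purple and named genes labelled. The Pearson r across genes was 0.815 and the slope 0.925.

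SON against vector in WT cells asked what added SON changed without the knockout. The genes with the smallest p were Osmr, the oncostatin M receptor, with no read in WT vector, the scavenger receptor Marco at 1.58 ± 0.24, nitric oxide synthase Nos2 at 1.89 ± 0.29, haptoglobin Hp (88.8 ± 10.1 CPM in WT vector and 177 ± 22.8 in WT SON) and the chromatin protein Hmga2 at -1.84 ± 0.27, with adjusted p from 0.0713 to 0.163, none of which passed. edgeR called 0 genes, with 912 at an unadjusted p under 0.05, and DESeq2 called 116 up and 41 down. Without WT vector 2, the library with the second lowest GC value, 6 genes passed, and the separate fit of genes without a GC-rich stretch called 31.

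Camera called lists in WT, where edgeR called 0 single genes over all tested genes. Macrophage and dendritic genes were higher, with a median log2 fold change of 0.75 and 8 of 14 up and 0 down adjusted over the list alone (camera adjusted p = 7.78e-15, adjusted p = 0.00868 with an estimated correlation). Restricted to its 9 members without a GC-rich stretch, the list passed at the preset correlation (camera adjusted p = 3.54e-08) but not with an estimated one (0.0916). Members of the macrophage and dendritic list not called over all genes include Adgre1, which encodes F4/80, at 0.89 ± 0.19. The receptor Csf1r, at 0.74 and also not called, belongs to the neutrophil and monocyte list. Megakaryocyte and erythroid genes were lower, with a median of -0.61 and 3 of 21 down and 0 up adjusted over the list alone (camera adjusted p = 2.04e-08, adjusted p = 0.004 with an estimated correlation), among them Car1 at -1.41 ± 0.29 and the erythroid transcription factor Gata1 at -1.18 ± 0.33. With only its 13 members without a GC-rich stretch, that list passed at the preset correlation (camera adjusted p = 0.00102) but not with an estimated one (0.0916). NF-kappaB genes were higher with a median of 0.48 and 10 of 22 up and 1 down adjusted over the list alone (camera adjusted p = 1.57e-11), including Il1a at 1.11 ± 0.20 and Il1b at 0.86, and the chemokine Ccl5 was at -1.68 ± 0.31. Camera also called interferon-response genes (2.61e-11), nucleic acid sensors (1.64e-08), neutrophil and monocyte genes (7.69e-07, 2 up and 0 down adjusted over the list alone, Itgam 0.67) and immediate early genes (1.57e-04, 2 and 0, Fos 0.77, Nr4a1 1.11) higher, and p53 targets lower (0.0101, 0 and 1, Ccng1 -0.51). Of these 6 lists none held with an estimated correlation: adjusted p = 0.113 for NF-kappaB, nucleic acid and neutrophil genes, 0.189 for immediate early genes and 0.347 for interferon and p53 genes.

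The 11 remaining lists did not pass in WT, with camera adjusted p of 0.117 for ribosomal proteins, 0.154 for mast cells, 0.219 for Myc targets and for stem cell genes, 0.287 for Atf4 targets, 0.323 for the m6A machinery, 0.396 for splicing and speckle genes, 0.731 for SON-sensitive transcripts and for stroma, 0.893 for the cell cycle and 0.969 for lymphoid genes. Cell cycle and lymphoid genes differed in sign between median, mean and test.

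SON against vector in cKO cells asked what added SON changed where Mettl3 transcripts were lower. The smallest p belonged to Trgc1 at -2.88 ± 0.38, the carbonic anhydrase Car1 at -2.18 ± 0.30, Ccl5 at -1.99 ± 0.31, Gm17060 at 1.63 ± 0.23 and the pseudogene Hspd1-ps3 at 1.04 ± 0.16, with adjusted p from 0.143 to 0.201, none of which passed over all genes. The separate fit of genes without a GC-rich stretch called 40 genes in cKO, among them Trgc1, Car1, Ccl5, Gm17060 and Hspd1-ps3 (adjusted p of 0.00572 to 0.0210). Over all genes edgeR called 0, with 986 at an unadjusted p under 0.05, DESeq2 called 111 up and 51 down, and 1 gene passed without WT SON 2. Megakaryocyte and erythroid genes were again lower as a list, with a median of -0.38 and 4 of 21 down and 0 up adjusted over the list alone (camera adjusted p = 8.35e-10, adjusted p = 0.00192 with an estimated correlation), with Car1, Gata1 at -1.61, glycophorin Gypa at -2.06 and the globin Hbb-bs at -2.37. Macrophage and dendritic genes were higher with a median of 0.54 and 1 of 14 up and 0 down adjusted over the list alone (camera adjusted p = 6.77e-06, adjusted p = 0.163 with an estimated correlation), Marco being at 1.40.

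Camera further called lower lists of ribosomal proteins (1.33e-18), Myc targets (6.72e-06), cell cycle (2.06e-04), interferon response (0.00409), mast cells (0.00174) and lymphoid genes (0.0127, 1 up and 3 down adjusted over the list alone) in cKO, and a higher list of stem cell genes (0.0307). With an estimated correlation none of them held, with adjusted p = 0.328 for ribosomal proteins, 0.228 for Myc targets, 0.325 for the cell cycle and mast cells, 0.646 for interferon, 0.214 for lymphoid and 0.406 for stem cell genes. The 10 others had camera adjusted p of 0.0948 for Atf4 targets, 0.116 for immediate early genes, 0.156 for p53 targets, 0.184 for SON-sensitive transcripts, 0.466 for splicing and speckle genes (Luc7l3 0.72 passing adjusted over the list alone) and for neutrophils, 0.539 for nucleic acid sensors, 0.813 for NF-kappaB, 0.946 for the m6A machinery and 0.952 for stroma. NF-kappaB and stroma genes differed in sign between median, mean and test.

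The SON effect averaged over both genotypes, a comparison added after the data were seen, showed more single genes. Among the 8249 genes without a GC-rich stretch 213 rose and 63 fell, 274 of these 276 with the same sign in both genotypes, and 0 passed the interaction test there. Ccl5, a chemokine of T cells and natural killer cells, fell by 1.80 ± 0.18, from 215 to 66.9 CPM in WT and from 476 to 120 CPM in cKO (adjusted p = 0.00139). Trgc1 fell by 2.08 ± 0.20 (adjusted p = 0.00139), and the erythroid genes Car1 and Gata1 fell by 1.75 ± 0.21 and 1.37 ± 0.19 (adjusted p = 0.00324 and 0.00529). Rises included Gpr183, an oxysterol receptor that guides immune cells, at 0.99 ± 0.12 (adjusted p = 0.00324), Spic, a transcription factor of red pulp macrophages, at 0.82 ± 0.10 (adjusted p = 0.00325) and the C-type lectin Clec4n at 0.98 ± 0.13 (adjusted p = 0.00394).

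Further named rises were the processed pseudogene Rps3a3 at 1.40, Gpnmb at 1.23, A4galt at 1.05, the macrophage metal transporter Slc11a1 (adjusted p = 0.0188), Dcstamp at 0.96, the RNA sensor Tlr13 at 0.88 and Bcl2a1d at 0.81. Further named falls were Pkd2l1 at -1.60, Ces2g at -1.36, Smim5 at -1.25, Rnase6 at -1.16, the interleukin-33 receptor Il1rl1 at -1.13 and Nkg7 of cytotoxic cells at -1.04. In the fixed lists 3 of 9 macrophage genes rose and 0 fell (Adgre1 0.76, H2-Aa 0.75, Cd74 0.57), 5 of 15 NF-kappaB genes rose and 1 fell (Il1a 0.78, Il1b 0.69, Ccl5 down), and 4 of 13 megakaryocyte and erythroid genes fell and 0 rose (Car1, Gata1, Gypa -1.40, Hbb-bs -1.52). Per-library scores changed for the macrophage list (0.68) and the megakaryocyte and erythroid list (-0.62, adjusted exact permutation p = 0.0475 each, two-sided), and no other list passed, NF-kappaB genes included (adjusted exact p of 0.333 or more). Gpnmb passed in 4, A4galt in 6, Pkd2l1 in 7 and Slc11a1 in 10 of the 12 fits that leave out 1 library, and the other 16 named genes in all 12. The count of 276 became 146 and 147 without WT vector 1 and 3, 137 and 124 without WT SON 2 and 3, 130 and 142 without cKO vector 1 and 3, and 110 and 101 without cKO SON 1 and 2.

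Over all 17259 genes the averaged comparison called 7, with 1305 at an unadjusted p under 0.05: Osmr at 3.57 (no read in WT vector), Marco at 1.49 and Il36g at 0.74 rose, and Trgc1 at -2.10, Ccl5 at -1.84, Car1 at -1.80 and the p53 target Ccng1 at -0.50 fell. DESeq2 called 286 up and 109 down. Of the fits that leave out 1 library, 155 genes passed without WT vector 2, 1 without cKO SON 2 and 0 without any of the other 10.

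**Figure D5:**
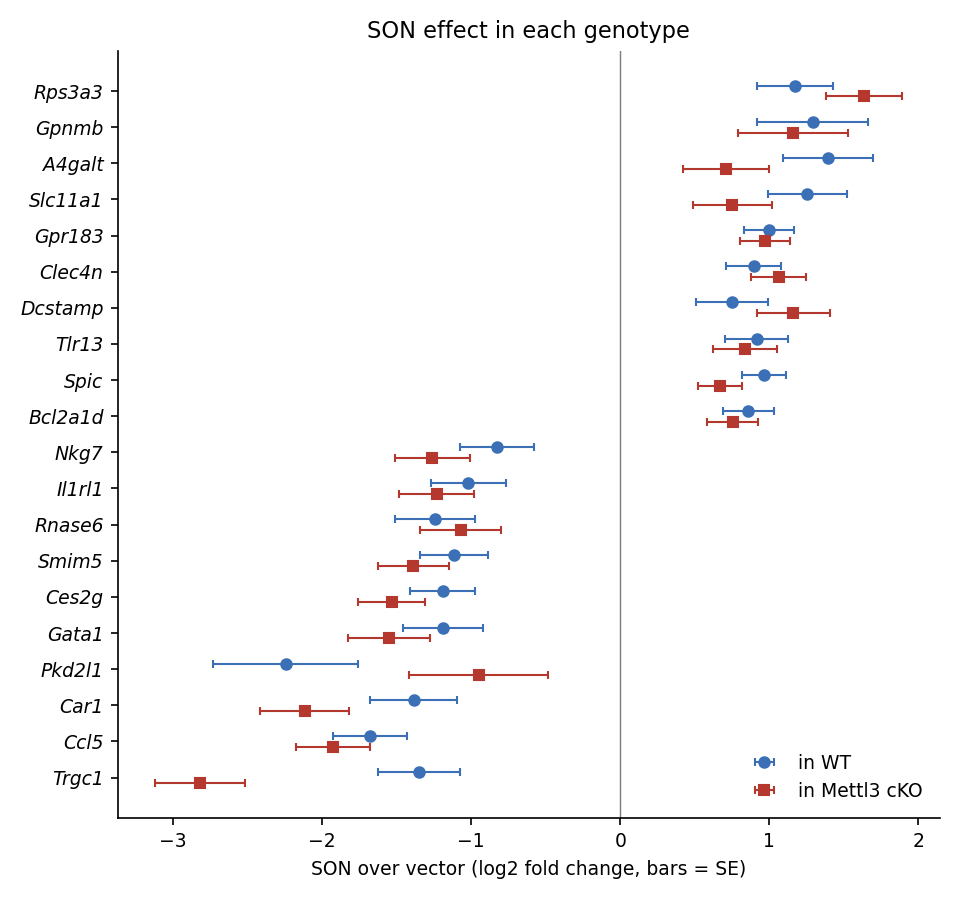
Log2 fold change of SON against vector in WT (blue circles) and in cKO (red squares) for the 20 named genes without a GC-rich stretch, with bars of 1 SE. Fitted over both genotypes, the values run from 1.40 for Rps3a3 to -2.08 for Trgc1.

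The interaction asked whether SON acted differently in the genotypes, at a viral SON transcript of 1.29% of all counts in WT SON and 2.59% in cKO SON, so it mixes genotype with SON level. edgeR called 0 genes, with 461 at an unadjusted p under 0.05, and DESeq2 called 4 up and 11 down. The smallest p belonged to Osmr at -6.98, which rests on a group without reads, Nos2 at -2.33, Dlg5 at -3.42, Tnf at -0.80 and the interferon-induced Slfn4 at -2.08, none of which passed (adjusted p of 0.242 or more). Interaction values of inflammatory genes, none of which passed, included Parp14 at -1.33 and the chemokines Cxcl2 at -1.26 and Cxcl10 at -1.40. Camera called 11 of the 19 lists for the interaction, and with an estimated correlation 0 were called (adjusted p of 0.266 or more). The median, mean and test differed in sign for p53 targets, the m6A machinery and splicing genes. Per-library scores differed by -0.53 for interferon-response genes (exact permutation p = 0.05), -0.54 for nucleic acid sensors (0.02) and -0.73 for neutrophil genes (0.05), and none passed after adjustment (adjusted exact p of 0.317 or more). Across genes the SON effects in WT and cKO had r = 0.19 and rho = 0.153. The remaining 2 relations compare contrasts that share a control group: SON in cKO against the genotype effect with vector had r = 0.044 where shared noise alone gave -0.504, and SON in WT against that effect had r = 0.204 where shared noise gave 0.488. The simulation held no genotype difference, which lowers the size of r, so these r values are not directly comparable. Covariances were 0.034 against -0.174 simulated for SON in cKO, and 0.151 against 0.167 simulated for SON in WT.

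TE subfamilies were compared between genotypes to ask whether transposon transcripts changed with the knockout. MER73, a long terminal repeat of the ERVL family, rose in cKO with vector by 4.83 ± 0.35, from 0.333 to 9.62 CPM (adjusted p = 8.34e-08), and with SON by 4.08, from 0.545 to 9.26 CPM. LTR33C rose by 2.26 and 2.72 and LTR41 by 1.52 and 1.84 with vector and SON. Both varied widely within some groups. In cKO vector LTR33C was at 18.0 ± 10.8 and LTR41 at 30.8 ± 18.1 CPM, and in cKO SON they were at 23.5 ± 1.90 and 38.6 ± 3.06 CPM. IAPLTR3 at 1.85 and MuRRS-int at 1.45 rose with vector, and UCON49 at 1.71 and MLTR25C at 1.66 with SON. Named falls with vector were MER57-int at -2.03, the mouse mammary tumour virus MMTV-int at -1.45, L1M3de at -1.33, RLTR47 at -1.29 and X2_LINE at -1.20. Named falls with SON were ORR1A0-int at -1.47, ERVB3_1-I_MM at -1.43, L1MEh at -1.39, RLTR30D_RN at -1.37 and RNERVK23-int at -1.33.

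Of 774 subfamilies 19 rose and 135 fell with vector, and 27 rose and 95 fell with SON. The direction of the families depended on scaling: the median log2 fold change with vector was -0.24 on gene-table library sizes and 0.001 with TMM on the TE table, which called 40 up and 15 down, and with SON the medians were -0.19 and -0.02, with 53 up and 36 down. On gene-table sizes 39 of 145 LINE/L1 subfamilies fell and 0 rose with vector, against 4 and 3 with TMM on the TE table. LTR/ERVK had 28 of 259 down and 10 up, against 3 and 17, and SINE/Alu 8 of 16 down and 0 up, against 0 and 0. TE reads were 48.5 ± 4.53, 47.2 ± 3.41, 40.7 ± 1.99 and 42.6 ± 2.62 per 1000 gene counts in WT vector, WT SON, cKO vector and cKO SON. The highest shares were in WT vector 2 (53.03) and WT SON 1 (51.1), the libraries lowest on the GC gradient. The TE falls may therefore follow that gradient as well as genotype, which was not tested. MER73, LTR33C, MuRRS-int and MMTV-int with vector, and MER73, LTR33C, MLTR25C, RLTR30D_RN and RNERVK23-int with SON, passed in all 12 fits that leave out 1 library. The count of 154 became 68, 52 and 233 without WT vector 1, 2 and 3, and 62 and 41 without cKO vector 2 and 3. The count of 122 became 35 and 68 without WT SON 1 and 3, and 49 and 51 without cKO SON 2 and 3.

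With edgeR on all 12 libraries and gene-table library sizes, SON changed no TE subfamily past the threshold. In WT edgeR called 0, with 25 at an unadjusted p under 0.05, and DESeq2 0, the smallest p belonging to RLTR4_MM-int at 0.40, LTR75 at 0.79, RLTR13D3 at 0.71, LTR40c at 0.84 and X15_LINE at 0.29. In cKO edgeR called 0, with 44 at an unadjusted p under 0.05, and DESeq2 0, with Lx5c at 0.38, MMERGLN_LTR at -0.48, RLTR30D_RN at -0.60, X12_LINE at -0.46 and RNERVK23-int at -0.48. The interaction also had 0 with both tools and 42 at an unadjusted p under 0.05. Averaged over genotypes edgeR called 0, with 43 at an unadjusted p under 0.05, and DESeq2 2. Without WT vector 2, 7 subfamilies passed for SON in WT and 1 for the interaction, and without WT SON 2 there was 1 for SON in WT. For the average 5 passed without WT vector 2 and 1 without cKO vector 2.

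Splicing was compared because both Mettl3 and SON act on mRNA processing. In cKO with vector, Fkbp7 exon inclusion (chromosome 2, 76667327 to 76667442) fell by 40.3 points ± 1.97, from 48.8% ± 0.98 to 8.5% ± 1.03 (adjusted p = 5.31e-04). Retention of a B3gnt8 intron (chromosome 7, 25627723 to 25628114) fell from 89.7% to 45.3%. A Uap1 exon (chromosome 1, 170147996 to 170148043) rose from 5.5% to 25.1% and a Ptk2b exon (chromosome 14, 66163025 to 66163150) rose by 23.0 points. With SON the Uap1 exon rose by 28.4 points and the Ptk2b exon by 27.7, while exons of Epb41 and Nf2 rose by 21.3 and 20.7 and an Mbnl1 exon was at -12.4. Uap1, Ptk2b, Epb41, Nf2 and Mbnl1 with SON were chosen after their values were seen.

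limma called 6 events higher and 15 lower with vector, and 24 higher and 38 lower with SON, and 10 were called in both, all with the same direction (0.00516 by independence). Other named events with vector were an Slco1a6 exon at -73.1, introns of Atxn1l at -73.0 and Ccpg1 at -33.2, an Nwd1 exon at 21.9, and splice sites of Zfp850 at 12.9 and Zkscan5 at 10.6. With SON they were Slco1a6 at -83.8, Podnl1 at -71.6, Tmem204 at -54.6, Procr at -52.4, Fhl4 at -46.0 and 46.0 for its paired donor sites, Tep1 at 47.5, Kif13b at 45.3, Pcgf2 at 33.3 and Epg5 at 30.1. Slco1a6 had 3 gene counts over the WT SON group, so its percentages there rest on few reads. Tep1, Pcgf2 and Epg5 had the same value in all 3 cKO SON libraries, and Tmem204 stayed under 1 CPM. The events of Fkbp7, Uap1 and the Mettl3 intron passed in all 12 fits that leave out 1 library with vector, and those of Uap1, Ptk2b, Epb41 and Mbnl1 with SON. The count of 21 became 99, 91 and 66 without WT vector 1, 2 and 3, and 153, 53 and 42 without cKO vector 1, 2 and 3. The count of 62 became 111, 199 and 102 without WT SON 1, 2 and 3, 102 without cKO vector 1, and 118, 115 and 133 without cKO SON 1, 2 and 3.

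For SON limma called 4 events in WT and 17 in cKO, with a test that recovered 3% of simulated changes of 20 points in WT. In WT, use of a Procr acceptor (chromosome 2, 155751348 to 155751464), in the gene for the stem cell marker EPCR, rose by 52.4 points ± 1.62 (adjusted p = 2.14e-05), and an Arfgap2 exon (chromosome 2, 91267336 to 91267416) fell by 27.1 points ± 1.60 (adjusted p = 0.00261). A Serpinb6a intron rose by 12.6 points and an Slc24a3 intron was at -14.1. In cKO 7 events rose and 10 fell, including a Crem intron (chromosome 18, 3288093 to 3295039) at -35.2, Tmem204 at -54.6, Fhod1 at -23.3, C430014B12Rik at -23.1, A930007I19Rik at -22.4, Tep1 at 46.0, Pcgf2 at 33.3, Epg5 at 29.6, Myh11 at 28.0 and Kdm1b at 15.6. The interaction called the Procr acceptor (-52.38 points ± 2.29, adjusted p = 2.49e-04) and the Arfgap2 exon (27.1 points ± 2.26, adjusted p = 0.0252). Procr was at 50.0%, 50.0% and 57.1% in WT SON 1, 2 and 3 and at 0% in the other 9 libraries, and Arfgap2 at 70.2%, 77.6% and 71.0% in WT SON and at 100% in the other 9. Groups without any spread enter the error of these tests, and the reads behind the percentages are unknown. Of the 17 events in cKO 12, and of the 4 in WT 3, were also called between genotypes with SON, a comparison that shares their SON libraries.

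The count of 4 became 72, 56 and 40 without WT vector 1, 2 and 3, and 56, 89 and 53 without WT SON 1, 2 and 3. In cKO 17 became 8 without WT vector 2, 10, 9 and 7 without WT SON 1, 2 and 3, 71, 53 and 30 without cKO vector 1, 2 and 3, and 61, 76 and 69 without cKO SON 1, 2 and 3. For the interaction 2 became 36, 31 and 17 without WT vector 1, 2 and 3, 41, 43 and 20 without WT SON, 39, 30 and 10 without cKO vector, and 31, 41 and 34 without cKO SON. Mean intron retention was 4.49% ± 0.58 and 4.37% ± 0.55 in WT vector and WT SON and 3.79% ± 0.03 and 3.93% ± 0.16 in cKO vector and cKO SON. It was highest in WT vector 2 (5.14%) and WT SON 1 (4.97%), the libraries lowest on the GC gradient, while WT SON 2 was at 3.87% and cKO SON 3 at 3.88%.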

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

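The tests of the GC gradient, of immunoglobulin segments and of pseudogenes in this part were chosen after the results were seen, as were the comparisons of SON averaged over genotypes whose splits are given, while the other counts over splits of the samples had been fixed before.

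These results differed between the genotypes by a test of the difference itself, and since the viral SON transcript made up 1.29% of all counts in WT SON and 2.59% in cKO SON, they may follow SON level as well as genotype. For the genotype by SON interaction camera gave an adjusted p of 7.81e-15 for interferon-response genes, 6.13e-07 for nucleic acid sensors, 2.20e-08 for NF-kappaB genes, 0.00774 for Myc targets, 5.68e-09 for ribosomal proteins, 0.00332 for the cell cycle, 0.0162 for Atf4 targets, 4.27e-06 for neutrophil and monocyte genes, 0.0303 for lymphoid genes and 0.0360 for macrophage and dendritic genes, the SON effect on each being lower in cKO than in WT, and 0.00313 for stem cell genes, where it was higher. With an estimated correlation every one of the 11 had an adjusted p of 0.266 or more, and directional fry gave 0.255 or more. The count of 11 lists became 6 without cKO vector 3 and 5 without cKO SON 1. Procr acceptor use differed between genotypes in its response to SON by -52.38 points, and Arfgap2 exon inclusion by 27.1 points, each from a group of 3 libraries against 9 libraries that had 1 value between them.

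The first pattern weighed is the large set of genes that differed between cKO and WT libraries, 1232 with vector and 4205 with SON. A separate fit of the 8249 genes without a GC-rich stretch argues against a loss limited to transcripts with such a stretch as the whole cause. It called 22.9% of them between cKO SON and WT SON (1347 of these 1889 also among the 4205). With vector it called 754 (423 of these also among the 1232). A loss graded by GC could also reach genes without a stretch, so the fit does not exclude it. With the GC correction 731 of the 1232 and 2799 of the 4205 were also called. An effect of handling apart from GC was not tested. For genes with a GC-rich stretch, among them Cebpb, Jund and Timp2, loss of GC-rich transcripts and an effect of Mettl3 on them cannot be told apart. The gradient spanned 1.36 among the 6 WT libraries, more than the genotype difference of 1.27, so a step of RNA or library handling could move these genes without any change in the cells. The gradient also differed between genotypes with an exact permutation p of 0.01, which leaves the Mettl3 knockout open, and the labels give no batch that would separate these.

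The second pattern is the fall of immunoglobulin transcripts in cKO, with Ighm at -3.21 with vector and -2.47 with SON. Segments with at least 200 counts in a library numbered 68 in WT vector and 49 in WT SON, and 79.49% of these 117 cases, some segments counted in both groups, had at most 10 counts in another library of the group, so the reads may come from a small number of antibody-secreting cells, each with its own segments. The median segment's lowest WT library held 0% of its highest, against 37.3% for Ighm. In cKO vector and cKO SON, with 21 such segments each, 71.4% and 95.2% had at most 10 counts in another library of the group. These values argue against even transcription in all cells as the source of the segment reads. For the constant regions, such as Ighm, lower transcription in all cells stays open. Fewer antibody-secreting cells cannot be told apart from less transcription in each. The Lin-negative sort should remove most B lineage cells, and Igkc (1421 ± 802 CPM in WT vector), Jchain (288 ± 168) and Mzb1 (27.3 ± 20.0) were present beside low Cd19 (1.57). Igkc, Jchain and Mzb1 were highest in WT vector 2 (2347, 481 and 50.4 CPM), which raises these means. Xbp1 and Txndc5, which other cells also express, were at 1.55 and 1.81 in cKO with vector, not called, and with SON Txndc5 rose by 2.36 (adjusted p = 0.0210) and Xbp1 was at 2.07, not called. Sdc1, another gene of antibody-secreting cells, was at 1.235 with vector and 2.11 with SON, neither called. Its lowest levels were in WT SON 1 (0.793 CPM) and WT vector 2 (1.25 CPM). Tnfrsf17, also of such cells, had 0.184 CPM in WT vector. Jchain, Pou2af1 and Irf4 were called lower in cKO with vector. Xbp1 and Txndc5 were also lowest in WT SON 1 (37.2 and 34.4 CPM) and WT vector 2 (46.5 and 46.4 CPM), the libraries lowest on the GC gradient, and whether the knockout lowered the number of such cells was not tested.

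The third pattern is the rise of some processed pseudogenes with SON, 73 up and 2 down among 1298 without a GC-rich stretch, while the class as a whole did not rise, with a median log2 fold change over all 1362 tested of -0.06 (-0.03 for other genes). Genomic DNA in the SON libraries is argued against by 1060 olfactory receptor genes, which had a mean of 0.0763 counts per gene and SON library (0.0804 in vector libraries), while the pseudogenes that rose gained a median of 52 counts per library. A fixed share of reads from the parent genes is argued against by the parents of 11 of them, with Rps6 the parent of 2, whose median log2 fold change was -0.18 where these pseudogenes had 1.23. RNA of the packaging cells carried over with the virus is a candidate explanation that stays open, since vector libraries received virus too and 0 of the pseudogenes that rose were absent from all 6 of them. No biological explanation was tested.

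Other splits of the same libraries into groups of equal size were fitted in the same way. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05, so the counts are given without a verdict on chance. For genes, as many were called in 1 of 10 splits for cKO against WT with vector (1232, highest other 443) and in 1 of 10 with SON (4205, highest other 0). For SON the real count was 0, which every split reaches, all 10 in WT (highest other 2535) and all 10 in cKO (highest other 0). The split with 2535 genes against a real count of 0 points to a structure of the WT samples that is not SON, and it is in these libraries that the GC gradient spans 1.36.

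For gene lists, 4 of 10 splits gave as many as SON in WT (8, highest other 10), 2 of 10 as many as SON in cKO (9, highest other 10), 2 of 10 as many as cKO with vector (8, highest other 8) and 3 of 10 as many as cKO with SON (7, highest other 9). For TEs it was 1 of 10 for cKO with vector (154, highest other 1), 1 of 10 with SON (122, highest other 0), 10 of 10 for SON in WT (0, highest other 23) and 10 of 10 for SON in cKO (0, highest other 0). For splicing it was 1 of 10 for cKO with vector (21, highest other 8), 1 of 10 with SON (62, highest other 5), 10 of 10 for SON in WT (4, highest other 28) and 1 of 10 for SON in cKO (17, highest other 12). A split with 28 events against 4 again points to a structure of the WT samples.

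For the interaction 100 splits were drawn. For its genes (highest other 438) and TEs (highest other 25) the real count was 0, which all 100 splits reach whatever they hold, so nothing follows about chance. Chance cannot be excluded for its splicing events (2, reached by 86, highest other 13), and the highest splits point to a structure of the samples. The 11 lists were reached by 3 of 100 splits (highest other 12), a share under 0.05 for camera at its preset correlation. That share was not adjusted over the splits tested, and 0 lists were called with an estimated correlation, so chance is not excluded for these lists. For SON averaged over genotypes the 7 genes of the full set were reached by 3 of 100 splits, also a share under 0.05. A highest other of 438 points to the same structure, so chance is not excluded for these genes either. For the 276 genes without a GC-rich stretch 1 of 100 splits, the real one, was as large, with a highest other of 8. That set of genes was chosen after the data were seen.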

How the results depend on the processing

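The GC correction, the genes without a GC-rich stretch (with lists there at an estimated correlation), the fits without 2 or 3 libraries, the comparison averaged over genotypes and the fits of gene lists without 1 library were chosen after seeing the data, the other alternatives before. Of 207 named gene results 121 were called and 38 of these kept their call under every alternative, 83 lost it under some, and 66 of the 86 that were not called passed under some. For TEs 20 of 24 were called and 9 kept, and for splicing events 44 of 45 and 6. No called gene, TE or event changed sign. Fewer libraries or fewer genes make a smaller test, but the counts also depended on which library was left out. For cKO with vector, 131 genes were called without cKO vector 2 and 3104 without cKO vector 1. The cause of these changes was not tested. Low counts limit the named V segments and events of poorly expressed genes, and the read depth of events is unknown.

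DESeq2 called 157 genes for SON in WT, 162 for SON in cKO, 3364 for cKO with vector, 15 for the interaction, 395 for SON averaged over genotypes and 603 for the latter among genes without a GC-rich stretch. With vector, cKO gave 767 genes without a count filter and 60 with only the groups compared. The stricter filter gave 50 genes for averaged SON. The GC correction gave 1 gene for SON in WT, 7 in cKO and 101 averaged. Genes without a GC-rich stretch gave 31, 40 and 276 for these, 754 for cKO with vector and 1889 with SON. For TEs, DESeq2 gave 2 for averaged SON, and TMM on the TE table gave 1 for SON in cKO, 55 for cKO with vector and 3 for averaged SON.

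With the replicate number as a replicate block, cKO with vector gave 329 genes and averaged SON 0 genes and 1 TE. Splicing under the replicate block gave 2 events for SON in WT, 1 for SON in cKO, 5 for cKO with vector, 13 with SON and 1 for the interaction.

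Without WT vector 2 and WT SON 1, SON in WT gave 4 genes, SON in cKO 6 and averaged SON 159. TEs were 3, 3 and 8 for these, 78 for cKO with SON and 1 for the interaction. Events were 97 for SON in WT, 6 in cKO, 102 for cKO with vector, 104 with SON and 50 for the interaction, and 11 lists were called for cKO with SON. Without cKO vector 1 as well, SON in WT gave 2 genes, cKO with vector 4883 and averaged SON 152. TEs were 3 for SON in WT, 1 for the interaction and 4 averaged. Events were 96, 56, 186, 113 and 80 in the order above, and 4 lists were called for cKO with SON.

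On a logit scale splicing gave 17 events for SON in WT, 41 for cKO with vector and 21 for the interaction. A minimum of 5 points gave 29 for SON in cKO, 35 for cKO with vector and 7 for the interaction. At 20 points there were 2 for SON in WT, 10 in cKO, 10 for cKO with vector and 31 with SON. Events with values in at least 2 libraries per group gave 40, 46, 55 and 116 for these and 52 for the interaction. The SD filter gave 2 for SON in WT, 11 for cKO with vector, 94 with SON and 1 for the interaction.

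Lists called with an estimated correlation were 2 for SON in WT, 1 in cKO and 0 for cKO with vector, cKO with SON and the interaction. Directional fry gave 3, 1, 5 and 0 for SON in WT, SON in cKO, cKO with vector and the interaction, and mixed fry 5, 3, 16, 19 and 0 with cKO with SON before the interaction.

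Across genes, r between the genotype effects was 0.947 at a mean CPM of at least 10, 0.91 for called genes, 0.765 with the GC correction, 0.686 without GC-rich stretches, 0.749 without 2 and 0.76 without 3 libraries. At that CPM, r was 0.286 between the SON effects, 0.396 for SON in cKO and 0.005 for SON in WT against the genotype effect. SON in cKO against the genotype effect turned to -0.104 without GC-rich stretches and -0.231 without 3 libraries. SON in WT against it was 0.338 for called genes and 0.319 without 2 libraries.

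Leaving out 1 library gave the following lowest and highest values. Genes ranged from 0 to 6 for SON in WT, 0 to 1 in cKO, 131 to 3104 for cKO with vector, 1128 to 5479 with SON, 0 to 1 for the interaction, 0 to 155 averaged and 101 to 361 averaged without GC-rich stretches. TEs ranged from 0 to 7 for SON in WT, 41 to 233 for cKO with vector, 35 to 126 with SON, 0 to 1 for the interaction and 0 to 5 averaged. Events ranged from 3 to 89 for SON in WT, 7 to 76 in cKO, 14 to 153 for cKO with vector, 50 to 199 with SON and 10 to 43 for the interaction. Lists ranged from 4 to 8 for cKO with vector, 4 to 9 with SON and 5 to 12 for the interaction. The correlation of the genotype effects ranged from 0.760 to 0.820, of the SON effects from 0.081 to 0.230, of SON in cKO against genotype from -0.222 to 0.096 and of SON in WT against genotype from -0.045 to 0.429.

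Values that were not called and changed sign, on the log2 scale, were these. Mettl3 for SON in WT was 0.163 without WT vector 2, 0.085 without WT SON 2 and 0.001 without 2 or 3 libraries (range without 1 library -0.139 to 0.163). Son was -0.047 without WT vector 2 and -0.015 without WT SON 3 for SON in WT, 0.071 without cKO vector 1 and 0.089 without 3 libraries for SON in cKO, 0.048 without 3 libraries for the interaction, and for cKO with vector 0.088 without WT vector 3, 0.03 and 0.084 without cKO vector 2 and 3 and 0.102 with the GC correction. Myc for SON in WT was 0.054, 0.118 and 0.196 without WT vector 1, WT vector 3 and WT SON 1. For cKO with vector it was -0.158 without WT vector 2, -0.181 without 2 and -0.235 without 3 libraries. For cKO with SON it was -0.265 without WT SON 1, -0.045 without cKO SON 3, -0.069 with the GC correction, -0.279 without 2 and -0.278 without 3 libraries. For the interaction it was 0.23, 0.057 and 0.04 without WT vector 2, WT SON 2 and WT SON 3. Without 1 library Son ranged from -0.047 to 0.281 for SON in WT, -0.458 to 0.071 in cKO and -0.446 to 0.088 for cKO with vector. Myc ranged from -0.534 to 0.196 for SON in WT, -0.158 to 0.483 for cKO with vector, -0.265 to 0.281 with SON and -0.499 to 0.23 for the interaction.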

Other observations

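The genes in this part were chosen after their values were seen, as were the tests of levels in other cell types, and no explanation was tested for them.

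Genes known from cytotoxic lymphocytes changed with SON in both directions. Ccl5 fell by 1.80, Trgc1 by 2.08 and the cytotoxic granule gene Nkg7 by 1.04 on the log2 scale over both genotypes (edgeR, genes without a GC-rich stretch), and Trgc1 went from 28.6 to 11.5 CPM in WT and from 12.9 to 1.75 CPM in cKO. Klrd1, a natural killer receptor, rose by 1.57, to 3.94 CPM in WT SON and from 0.690 to 2.26 CPM in cKO. The T cell receptor component Cd3e had 0 CPM in WT vector, cKO vector and cKO SON and 0.0347 in WT SON, and Gzma was at 0.0396 CPM or less in every group.

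The genotype also moved Ccl5, in the other direction, by 1.15 ± 0.30 with vector (adjusted p = 0.0484), while with SON it was 0.84 ± 0.30 and not called (adjusted p = 0.0646), with an interaction of -0.31 ± 0.42 for Ccl5, not called. Irf4, a transcription factor of plasma cells and of dendritic cell development, fell in cKO by 1.43 ± 0.24 with vector (adjusted p = 0.0133) and by 1.64 ± 0.24 with SON (adjusted p = 0.00427). Prdm1, another plasma cell factor, fell by 1.35 with SON (adjusted p = 0.0173) and was -0.64 ± 0.31 with vector, not called, with an interaction of -0.72 ± 0.44 that was not called. Fcer2a, the low-affinity IgE receptor of B cells, rose by 2.66 ± 0.35 with vector, from 2.38 to 15.1 CPM, and by 1.52 ± 0.33 with SON. Of genes of mature B cells, Cd19 was at 0.983 to 2.41 CPM and Pax5 at 0.0712 CPM or less, while Cd79b was at 16.7 to 26.9 CPM, Cd37 at 51.6 to 84.8 CPM and Cd74, which macrophages also express, at 554 to 1102 CPM.

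Mettl3 itself showed changes at more than 1 place in its transcript. Exon 4 inclusion stayed at 71.2% and 59.3% in the cKO groups and Mettl3 level at 30.8 and 25.6 CPM. Reads of exon 4 therefore remained in cKO libraries.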
